A study of Mus musculus with 24 samples.

How the data were processed

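RNA from cDC1 and cDC2 sorted by flow cytometry from mouse spleens was sequenced in 24 libraries, per the labels. The mice were 6 to 12 weeks old and carried either floxed Zeb2 or an inducible Zeb2 transgene in Rosa26, with or without CD11c-driven Cre, per the labels. Per the labels' protocols, 4 ng of RNA was amplified with a SMART-Seq v4 kit, libraries had 15 PCR cycles and 250 bp inserts, and 75 bp reads were run on 2 flow cells. Per the submitters' processing notes, reads were checked with FastQC 0.11.4, trimmed with Trimmomatic 0.35, aligned with TopHat2 2.1.0 to mm10 and handled with SAMtools 0.1.18. The deposited files hold integer counts per gene symbol as made by the authors, without scaling, for 24421 symbols. The counting program, the annotation and the strand setting are not given in the sources used here. Each file also has 5 lines for reads in no gene, which were left out of totals and tests. Reads in no feature came to 10.43 to 15.68% and ambiguous reads to 0.9702 to 1.086%, and the line for reads without a unique place was 0 in all libraries. Xist had at most 3 counts and Ddx3y at least 1286 in any library, so all libraries are male.

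Libraries were grouped by subset, line and Cre from the labels, 2 per Cre-negative and 4 per Cre-positive group. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr over the 8 groups (minimum count 10, minimum total 15), leaving 13166, and scaled by TMM (factors 0.9246 to 1.074). A quasi-likelihood model with 8 group means was fitted to the 24 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were Cre-positive against Cre-negative within each subset and line, control cDC2 against control cDC1, the difference of the Cre effect between subsets (cDC2 minus cDC1), and the controls of the transgene line minus those of the deletion line. The CPM values printed are TMM-scaled, and positions are those of GRCm38.p6, the assembly of mm10. Principal components used log2 CPM with a prior count of 2, and log2 CPM values of single libraries a prior count of 0.5. Chi-square values between replicates used genes with a summed count of at least 20. Counting intervals are at 95%, and floors are 3 counts per library.

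Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 76 tests (19 lists in the 4 Cre comparisons), with camera at an estimated correlation and fry beside it. The lists were cDC1 identity, cDC2 identity, pDC, monocyte, red pulp macrophage, B cell, T cell, NK cell, neutrophil, erythroid, cell cycle, interferon response, maturation, MHC class II, epithelial genes repressed by ZEB factors, E protein and Id, lineage transcription factors, TGF-beta, and early response and heat shock. Subset signatures were genes at least 4-fold apart between the control subsets of the line not being tested, adjusted over 8 tests. Named genes were Zeb2 and Id2, up to 4 passing members of each list with the smallest p, the 8 highest and 8 lowest fold changes among passing genes with an average log2 CPM of at least 2 and no overlap between groups, 4 in each direction for interactions, and up to 6 in each direction for genes moving oppositely. Replicate numbers were taken to pair cDC1 with cDC2 libraries in the transgene line, where all 6 pairs deviated together from their group means (r of 0.112 to 0.156, each over 0.1). With 2 controls per group, both pairs of controls give the same r by construction and count as 1. In the deletion line the Cre-positive pairs had r of 0.199 to 0.301, above those of the transgene line, and the controls -0.0406. That reading by line was made after the blocked fit had been seen. Groups, comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except where stated. Alternatives were DESeq2 size factors or DESeq2 itself, no low-count filter or a stricter one (at least 5 CPM in 4 libraries), a fit of the compared libraries alone, a block on replicate number, a 2-fold minimum, pooled controls, signatures from both lines, other set tests, and leaving out each library in turn.

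The procedure was tested on simulated counts drawn from the libraries' means and depths, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. The changed genes had a simulated baseline of at least 1 CPM in the compared groups, so recovery of changes in scarcer genes was not measured. Recovery of the 2-fold and 4-fold changes was 73 and 97% in cDC1 with the deletion (13000 genes tested), 78 and 96% in cDC1 with the transgene (12990), 80 and 93% in cDC2 with the deletion (12944) and 83 and 96% in cDC2 with the transgene (12989). It was 90 and 99% for the control subsets (12968), 59 and 87% for the interaction in the deletion line (12914) and 57 and 90% in the transgene line (12979). For the line controls it was 67 and 92% in cDC1 (12992) and 68 and 94% in cDC2 (13003). Between 2 and 16 unchanged genes were called in each. A list of shifted genes was called by camera and by fry in each Cre comparison, and 1 of 18 unchanged lists was called by camera in cDC1 with the transgene. These lists were random genes simulated independently of each other. Members of the real lists vary together, with an estimated correlation of 0.545 for the cell cycle list in cDC1 with the transgene. The simulation therefore cannot show how often camera at the preset correlation calls such lists falsely.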

Results

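Conventional dendritic cells (cDCs) of both splenic subsets were profiled by RNA sequencing in untreated C57Bl/6 mice. The cDC1 subset is known for presenting antigens of dead cells to CD8 T cells, and the cDC2 subset for priming CD4 T cells. Zeb2 encodes a zinc-finger transcription repressor, and per the series title the study asked how it acts on dendritic cell development through Id2, an inhibitor of E protein transcription factors. In the deletion line, Cre recombinase driven by CD11c sequences removed part of a floxed Zeb2 gene. In the transgene line, the same driver switched on a Zeb2 transgene in the Rosa26 locus. Each line came with Cre-negative littermates as controls. The 24 libraries formed 8 groups, with 2 control libraries and 4 Cre-positive libraries for each subset and line. Library totals over genes ran from 21972763 to 36094786 counts, and 13396 to 14260 genes had at least 1 count in a library. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries only. Of the variance in log2 CPM (counts scaled by library size), 63.5% lay on a first principal component and 7.13% on the next. The 28 pairs of replicates within groups all differed by more than sampling noise, with chi-square values per gene of 10.11 to 51.1. Counting intervals and floors given below cover counting error alone, not the spread between libraries.

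Zeb2 itself was low in cDC1 and high in cDC2 of the controls. It stood at 0.488 and 2.56 CPM in the cDC1 control replicates 1 and 2 of the deletion line, and at 3.25 and 2.36 CPM in those of the transgene line. In control cDC2 it stood at 176 and 132 CPM in the deletion line and at 104 and 104 CPM in the transgene line. Cre-positive cDC2 of the deletion line held 38, 41.4, 33 and 30.7 CPM, a mean of 35.8 ± 4.82 (SD, n = 4) against 154 ± 31.1 (SD, n = 2), which was 4.31-fold lower. In Cre-positive cDC1 of the transgene line, Zeb2 stood at 44.3, 45, 46.2 and 41.3 CPM, 15.6-fold higher than in their controls. In Cre-positive cDC2 of the transgene line it stood at 151, 152, 148 and 159 CPM. The cDC1 of the deletion line, already low without Cre, held 0.685, 0.457, 1.06 and 2.67 CPM with Cre. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Zeb2 fell by 2.11 on the log2 scale in cDC2 with the deletion (SE 0.27, adjusted p = 5.13e-05) and rose by 3.96 in cDC1 with the transgene (SE 0.39, adjusted p = 3.88e-07). The log2 fold change was 0.56 in cDC2 with the transgene (adjusted p = 0.618; 0.55 and adjusted p = 0.0254 in a fit of those 6 libraries alone) and -0.31 in cDC1 with the deletion (adjusted p = 1.0; 1.31 without control replicate 2). In exact two-sided permutation tests over 15 assignments of the libraries, p was 0.867 in cDC1 with the deletion and 0.0667 in each of the other comparisons, the smallest value 4 against 2 libraries allow. The whole gene, on chromosome 2 from 44983512 to 45117442 in mm10, was counted, so reads from exons that Cre leaves in place are included and the residual count is no measure of undeleted cells.

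Id2 ran the other way. It was 4.41-fold lower in control cDC2 than in control cDC1, at 313 ± 94.9 against 1360 ± 155 CPM (SD, n = 4 each). Deletion of Zeb2 raised it in cDC2 from 252 ± 90.0 (SD, n = 2) to 552 ± 56.1 CPM (SD, n = 4), 2.19-fold higher, and the transgene lowered it in cDC1 from 1270 ± 66.7 to 842 ± 34.3 CPM, 1.51-fold lower. With the same test, the log2 fold change was 1.13 (SE 0.16, adjusted p = 0.000141) in cDC2 with the deletion and -0.59 (SE 0.15, adjusted p = 0.0168) in cDC1 with the transgene. The second call was lost without control replicate 1 (adjusted p = 0.0637) or 2 (adjusted p = 0.153) of that group. Id2 did not pass in cDC1 with the deletion (log2 fold change -0.07, adjusted p = 1.0; 0.06 without control replicate 1) or in cDC2 with the transgene (-0.22, adjusted p = 0.744). Id2 lies on chromosome 12 from 25093799 to 25096092.

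**Figure D1:**
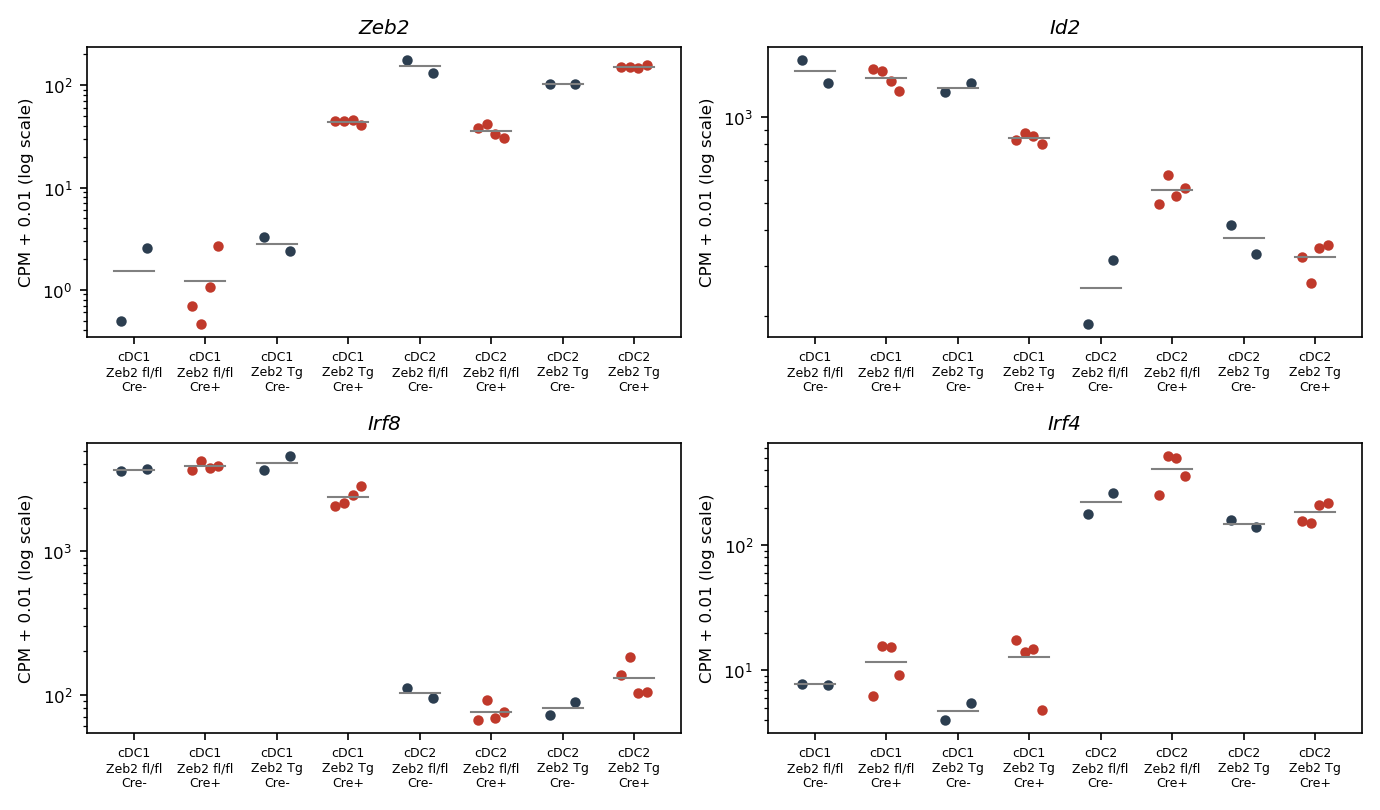
CPM of Zeb2, Id2, Irf8 and Irf4 in each of the 24 libraries by subset, line and Cre (log axis after adding 0.01 CPM; points are libraries, grey bars group means, red Cre-positive). Zeb2 falls from a mean of 154 to 35.8 CPM in cDC2 with the deletion and rises from 2.81 to 44.2 CPM in cDC1 with the transgene.

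The comparison of control cDC2 with control cDC1 set the baseline for the subsets. All 19 tested genes of the cDC1 identity list were lower in cDC2. The chemokine receptor Xcr1 was 229-fold lower (4.66 ± 1.42 against 1070 ± 130 CPM, SD, n = 4 each), and Irf8, a transcription factor that cDC1 need, was 42.7-fold lower. Of 20 tested cDC2 identity genes, 18 were higher and 1 lower in cDC2, with Sirpa, an inhibitory receptor, 236-fold higher (1380 ± 119 against 6.03 ± 2.62 CPM). Irf4, a factor of cDC2 function, was 30.1-fold higher. Among genes with an average log2 CPM of at least 2, counts in both groups and no overlap between them, the largest differences were Clec4a4, Dscam, Sirpb1a and Sucnr1 on the cDC2 side and Dkk3, Gcsam, P3h2 and Cd207 on the cDC1 side. Dkk3 had 2 counts in all cDC2 controls and 8335 in cDC1, a ratio of 4710 with a 95% counting interval of 1300 to 38900, and Homer2 and Cyp8b1, with no count in cDC2, were at least 131-fold and at least 82.1-fold lower there against a floor of 3 counts per library. Clec4a4, Sirpb1a and Sirpb1b belong to families of near-identical genes, so the split of reads within each family is uncertain.

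The other lists also held genes that differed between the control subsets, in a comparison where 7035 of 13166 genes did. Of 20 interferon response genes, 14 were higher and 3 lower in cDC2 (Rtp4 133-fold and Ddx58 73.3-fold higher), with an adjusted p of 8.6e-06 by camera, limma's competitive test, and adjusted p = 0.338 with an estimated correlation. Of 17 monocyte genes, 13 were higher and 1 lower (Csf1r 35.5-fold and Cx3cr1 79.1-fold higher, adjusted p = 1.26e-07, and 0.00511 with an estimated correlation). Of 20 dendritic cell lineage transcription factors, 12 were higher and 5 lower (adjusted p = 0.258), and of 14 major histocompatibility complex (MHC) class II genes, 6 were higher and 3 lower (adjusted p = 0.021, and adjusted p = 0.779 with an estimated correlation). Of 19 plasmacytoid dendritic cell (pDC) genes, 10 were higher and 5 lower, among them Tlr7, a receptor for single-stranded RNA (394-fold higher), and Spib (36.9-fold higher), and the list did not pass (adjusted p = 0.245). Of 15 red pulp macrophage genes, 7 were higher and 2 lower (adjusted p = 0.0752), of 11 B cell genes 5 and 1 (0.0507), of 18 transforming growth factor beta (TGF-beta) genes 8 and 2 (0.211), of 20 early response and heat shock genes 9 and 4 (0.537), of 18 maturation genes 8 and 5 (0.913), and of 20 cell cycle genes 5 and 2 (0.651). The T cell, NK cell, neutrophil, erythroid, epithelial and E protein lists had 4, 2, 2, 1, 2 and 3 members higher and 1, 1, 0, 0, 1 and 2 lower (adjusted p of the lists 0.636, 0.916, 0.537, 0.913, 0.651 and 0.845). Adjusted over the list alone, the counts were the same except for 6 lower pDC genes and no lower T cell or epithelial gene. The sign of the test differed from that of the median for maturation (median log2 fold change 0.30, test down), NK cell (-0.38, test up), erythroid (-0.64, test up) and E protein genes (0.04, test down). In all, 3634 of 13166 tested genes were higher in cDC2 and 3401 in cDC1 at an adjusted p under 0.05, and 1828 and 1193 of these differed at least 2-fold.

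Gain of Zeb2 in cDC1 moved genes of both subset programmes. The lectin receptor Clec7a rose 57.4-fold (146 ± 74.3 against 2.55 ± 0.02 CPM, SD, n = 4 and 2), Sirpa 10.9-fold and Cd4 6.67-fold, while Gcsam fell 5.69-fold (74.8 ± 9.43 against 425 ± 27.7 CPM), Tlr3, a receptor for double-stranded RNA, 2.29-fold, and Irf8 1.74-fold (2370 ± 344 against 4130 ± 631 CPM). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 472 genes were higher and 450 lower, and 228 and 179 of these changed at least 2-fold. Of 19 tested cDC1 identity genes, 11 fell, none rose and 8 did not pass (13 fell adjusted over the list alone). Those with the smallest p were Gcsam, Tlr3, Hepacam2 (2.73-fold lower) and Tlr11 (1.68-fold lower; adjusted p = 0.0524 without control replicate 2). The list was lower as a set by camera (median log2 fold change -0.50, adjusted p = 5.98e-13, and adjusted p = 0.0114 with an estimated correlation). Of 20 cDC2 identity genes, 11 rose and 9 did not pass, with the same counts adjusted over the list alone, and those with the smallest p were Cd300a (4.44-fold), Cd4, Sirpa and Clec4a2 (12.2-fold). Their median log2 fold change was 1.35 (adjusted p = 1.48e-13, and adjusted p = 0.0714 with an estimated correlation). Clec4a2 lies in a family of similar genes and its count is uncertain. Cre-positive replicates 1 and 2 of this group differed less from each other (chi-square per gene 14.21) than the other pairs did (41.11 to 51.1), and the lists moved with these libraries. In replicates 1 to 4 the mean log2 CPM of the cDC2 identity list was 4.28, 4.18, 3.69 and 2.98 (2.38 and 2.47 in the controls), and that of the cDC1 identity list 8.35, 8.39, 8.57 and 8.70 (9.13 and 9.32).

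Among genes with an average log2 CPM of at least 2 and no overlap between groups, Ptger3 and Clec4a4 rose most. The prostaglandin receptor Ptger3 had 944 counts with the transgene and 3 in the controls, a ratio of 127 (95% counting interval 43.4 to 618), Clec4a4, also on the cDC2 identity list, 289 and 1 (ratio 117, 20.8 to 4630), and Cd300ld 312 and 2 (ratio 63.1, 17.3 to 523). Ifit3b rose 35.2-fold, Ddx58, which senses viral RNA, 30.0-fold, and Clec4a1 and Sirpb1a 26.8-fold each. Ifit3b and Ptger3 had no count in control replicate 2, and Cd300ld and Clec4a4 none in control replicate 1, so the size of these changes rests on a single control library. Ifit3b shares sequence with Ifit3, Clec4a1 and Clec4a4 with each other's family, and Sirpb1a with Sirpb1b, so these counts are uncertain. The genes that fell most by the same choice were Ttc39a (16.6-fold, 11.6 ± 2.87 against 193 ± 26.2 CPM), Dnajc22 (16.6-fold), Ltbp2 (13-fold), Fcrla (11.9-fold), Dkk3 (11.4-fold), Rtn4rl1 (9.93-fold), Asprv1 (6.33-fold) and Actn1 (6.06-fold). Of these, Dnajc22 and Rtn4rl1 were higher in control cDC2 than in control cDC1 (log2 fold change 3.08 and 1.76), so their fall was not a shift towards cDC2.

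Interferon response and cell cycle genes rose in the same libraries. Of 20 interferon response genes, 10 rose and 10 did not pass (14 rose adjusted over the list alone), with the smallest p for Ddx58, Oasl2 (11.9-fold), Rtp4 (18.2-fold) and Oas1a (5.73-fold) (median log2 fold change 1.53, adjusted p = 2.03e-17, and adjusted p = 0.0664 with an estimated correlation). The mean log2 CPM of this list was 4.21 and 4.35 in Cre-positive replicates 1 and 2 and 3.55 and 3.62 in replicates 3 and 4 (2.17 and 2.14 in the controls), and Rtp4 stood at 17.8, 16.8, 6.9 and 5.04 CPM. The same list was higher in control cDC2 than in control cDC1 by camera, though not with an estimated correlation (adjusted p = 0.338). Of 20 cell cycle genes, 9 rose and 11 did not pass (14 rose adjusted over the list alone), among them Aurka, a mitotic kinase (1.89-fold, 35.2 ± 3.88 against 18.6 ± 1.85 CPM), and Ccnb1 (1.89-fold; adjusted p = 0.0943 and 0.124 without control replicate 1 or 2). The median log2 fold change of that list was 0.60 (adjusted p = 1.24e-09, and adjusted p = 0.487 with an estimated correlation), and its mean log2 CPM in replicates 1 to 4 was 6.30, 6.28, 6.69 and 6.52 (5.88 and 5.79 in the controls). Of 17 monocyte genes, 3 rose: Csf1r, the receptor for macrophage colony-stimulating factor (3.65-fold), Ms4a4c (5.02-fold; log2 fold change 2.33, and 3.50 without control replicate 1) and Cd300e (2.24-fold; adjusted p = 0.162 without control replicate 1). That list had an adjusted p of 0.012, and adjusted p = 0.313 with an estimated correlation. Of 15 red pulp macrophage genes, Adgre1 (7.81-fold), Hmox1 (3.06-fold) and Spic (3.90-fold; adjusted p = 0.127 without control replicate 1) rose, and 4 rose adjusted over the list alone (adjusted p = 0.0456, and adjusted p = 0.785 with an estimated correlation). In replicates 1 to 4 the mean log2 CPM was 3.21, 3.34, 3.46 and 3.36 for the monocyte list (3.19 and 2.85 in the controls) and 2.89, 3.18, 1.93 and 3.21 for the macrophage list (2.31 and 2.81), with replicate 3 below both controls. Adgre1 was also 49.7-fold higher in control cDC2.

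Maturation genes fell in these cDC1. Of 18 maturation genes, 4 fell: Ccl22 (3.08-fold, 30.5 ± 10.1 against 93.8 ± 4.82 CPM), Cd200 (2.09-fold), Ccr7 and Fscn1, the last pair with adjusted p of 0.264 and 0.201 without control replicate 1 and 0.0812 and 0.0533 without control replicate 2. Leaving out Cre-positive replicate 3 gave 0.102 and 0.0567 for this pair, and leaving out replicate 4 gave 0.0809 and 0.057. The list was lower by camera (adjusted p = 0.00232, and adjusted p = 0.785 with an estimated correlation), and adjusted over the list alone 1 rose and 6 fell. Its mean log2 CPM was 5.24 and 5.22 in replicates 1 and 2 and 4.53 and 4.74 in replicates 3 and 4 (5.50 and 5.38 in the controls). Of 20 lineage transcription factors, 1 rose and 4 fell (3 and 4 adjusted over the list alone), the falls being those of Irf8, Zbtb46, Rbpj and Id2. The adjusted p without control replicate 2 was 0.143 for Irf8, 0.0655 for Zbtb46, 0.0533 for Rbpj and 0.153 for Id2, and without control replicate 1 it was 0.0637 for Id2. The median of that list was -0.03 and its mean 0.29, with the test down and not past the threshold. Of 14 MHC class II genes, Lgmn and Ctss, proteases of antigen processing, rose 2.49-fold and 1.35-fold. Of the 3 that fell, H2-Ob fell 1.69-fold and H2-Oa 1.32-fold (adjusted p of H2-Oa 0.227 without control replicate 2). Adjusted over the list alone, 4 rose and 5 fell. Of 19 pDC genes, Fcrla fell and Tlr7 rose 14.9-fold (adjusted p = 0.0709 and 0.0719 without control replicate 1 or 2), while Pacsin1 fell 4.3-fold (adjusted p = 0.437 without control replicate 2). In all, 1 rose and 3 fell (5 rose and 4 fell adjusted over the list alone; median log2 fold change 0.19, mean -0.11, test down). Of 18 TGF-beta genes, Smad7 rose 2.25-fold and 1 other fell, the same counts adjusted over the list alone. Of 11 B cell, 13 T cell and 11 NK cell genes, 1 each fell, also adjusted over the list alone. These were Ms4a1, Cd8b1 (adjusted p = 0.193 without control replicate 1) and Prf1 (3 counts against 31, a ratio of 25.5 with a 95% counting interval of 7.97 to 131). Ms4a1 kept its call only without Cre-positive replicate 2 (adjusted p 0.0514 to 0.286 in the other 5 leave-one-out fits), and Prf1 only without control replicate 2 (0.0551 to 0.906). No neutrophil, erythroid, epithelial, or early response and heat shock gene passed, and adjusted over the list alone 1 epithelial gene rose and 1 fell. The E protein list had the fall of Id2 alone among 6.

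The count of changed genes in cDC1 with the transgene rested in part on the 2 controls. There were 297 genes higher and 287 lower without control replicate 1, without control replicate 2, 264 and 212, in a fit of those 6 libraries alone 251 and 299, and with the controls of both lines pooled 1059 and 856.

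In cDC2 with the deletion, monocyte and cell cycle genes were lower. Whether genes changed within cells or the make-up of the sorted cells changed was not tested for this comparison. Lyz1 and Lyz2, lysozyme genes of myeloid cells, fell 6.26-fold and 3.74-fold (Lyz2 578 ± 143 against 2160 ± 327 CPM, SD, n = 4 and 2), Cx3cr1, the fractalkine receptor, 4.27-fold, and Csf1r 1.86-fold. Ttc39a rose 21.6-fold (15.2 ± 6.98 against 0.699 ± 0.119 CPM), Fcrla 13-fold, and Epcam, an adhesion molecule of epithelia and Langerhans cells, 3.93-fold (48.2 ± 7.46 against 12.3 ± 1.38 CPM). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 307 genes were higher and 379 lower, and 125 and 119 of these changed at least 2-fold. Of 17 monocyte genes, 6 fell, none rose and 11 did not pass (7 fell adjusted over the list alone). The list was lower by camera (median log2 fold change -0.21, adjusted p = 2.75e-09, and adjusted p = 0.0108 with an estimated correlation). The adjusted p of Csf1r was 0.0749 without control replicate 1. Lyz1 and Lyz2 are close copies, and the share of each is uncertain. Of 20 cell cycle genes, 17 fell and 3 did not pass (19 fell adjusted over the list alone), with the smallest p for Mcm3 (1.78-fold, 120 ± 19.2 against 214 ± 6.22 CPM), Mcm5 (1.68-fold), Ccna2 (2.20-fold) and Aurka (1.78-fold) (median log2 fold change -0.83, adjusted p = 9.88e-24, and adjusted p = 0.0667 with an estimated correlation). Mcm5 and Aurka had an adjusted p of 0.05 and 0.053 without control replicate 1.

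Subset identity genes in these cDC2 went in both directions. Of 19 cDC1 identity genes, 4 rose and 3 fell (5 and 4 adjusted over the list alone). Snx22 rose 4.66-fold (12.8 ± 2.07 against 2.75 ± 0.298 CPM) and Id2 2.19-fold, while Clec9a, a receptor for dead cells, fell 5.48-fold (2.69 ± 0.961 against 14.8 ± 4.03 CPM), and Cd36 3.36-fold. The list as a set did not pass (median log2 fold change 0.16, adjusted p = 0.476). Of 20 cDC2 identity genes, Clec12a fell 1.75-fold and 19 did not pass, the same count adjusted over the list alone (adjusted p of the list 0.698; median 0.06, test down). Mmp9, a protease on the neutrophil list, fell 7.04-fold (11.6 ± 6.04 against 81.4 ± 7.66 CPM) and was the single neutrophil gene of 9 to pass, also adjusted over the list alone. Beside Clec9a, Lyz1, Mmp9 and Zeb2, the genes that fell most among those with an average log2 CPM of at least 2 and no overlap between groups were Gp2 (12.6-fold), Itga8 (7.42-fold), Adamdec1 (6.80-fold; adjusted p = 0.0512 without control replicate 2) and Dab2 (5.34-fold). Among those that rose most by the same choice were Plce1 (19.3-fold; no count in control replicate 1), P3h2 (11.9-fold; no count in control replicate 2, and adjusted p = 0.0514 without it), Clec4b2 (130 counts against 3, ratio 22.3, 95% counting interval 7.45 to 109) and Igf2r (76 against 2, ratio 19.5, 5.22 to 164). The last pair lost its calls without control replicate 1 (adjusted p = 0.0599 and 0.242) or 2 (0.107 and 0.0593). Cox6a2, Itgad, Plcb1 and Plcb4 also rose and are described with the transgene line.

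Markers of other cells were raised in part in the same cDC2. Of 11 B cell genes, Ms4a1, which encodes CD20, rose 10.7-fold (186 ± 21.2 against 17.3 ± 7.35 CPM) and Fcer2a, which encodes CD23, 6.64-fold. Their adjusted p was 0.05 and 0.0675 without control replicate 1. The list did not pass (median log2 fold change 0.99, adjusted p = 0.293), and adjusted over the list alone 2 rose and 1 fell. Among members that did not pass over all genes, Cd22 (71.8 against 127 CPM) and Cd79b (28.4 against 40.6 CPM) were lower and Blk (17.9 against 8.32 CPM) higher. Ms4a1 stood at 57.2 and 33.9 CPM in control cDC1 of the deletion and transgene line, above 17.3 and 28.1 CPM in control cDC2. Of 19 pDC genes, Cox6a2, Fcrla and Ly6a rose (3 adjusted over the list alone; Ly6a adjusted p = 0.219 without control replicate 1, and log2 fold change 3.97 against 2.54 without control replicate 2). The pDC list was higher by camera (median log2 fold change 0.27, adjusted p = 0.00188, and adjusted p = 0.495 with an estimated correlation). Fcrla was 18.9-fold higher in control cDC1 than in control cDC2. Of 15 red pulp macrophage genes, Fcna (4.51-fold) and Slc40a1 (3.81-fold) rose and Trf fell 1.54-fold, the same counts adjusted over the list alone, and Trf had an adjusted p of 0.145 without control replicate 1. Fcna kept its call only without Cre-positive replicate 1 (0.0632 to 0.373 in the other 5 fits), and Slc40a1 only without that library or control replicate 2 (0.0543 to 0.424). Of 5 tested erythroid genes, Car2 (3.02-fold; 47.3 ± 4.36 against 15.6 ± 1.80 CPM) and Slc4a1 rose, also adjusted over the list alone. Car2 lost its call in each of the 6 leave-one-out fits (adjusted p 0.0619 to 0.373), and Slc4a1 without control replicate 1 (0.334) or 2 (0.206) or Cre-positive replicate 1 (0.0615) or 4 (0.114). Slc4a1 had 148 counts with the deletion and none in these controls, at least 12.6-fold against the floor, and with the controls of both lines pooled its log2 fold change was -0.08. Of 13 T cell genes, Cd8b1 rose 4.03-fold (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.233 and 0.0904 without control replicate 1 or 2, and log2 fold change -0.03 with pooled controls). No NK cell gene passed.

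The remaining lists held few calls in cDC2 with the deletion. Of 18 maturation genes, Ccl22 rose 2.42-fold (2 rose adjusted over the list alone) and kept its call only without Cre-positive replicate 1 (adjusted p 0.0638 to 0.499 in the other 5 fits), with an adjusted p of the list of 0.012, and adjusted p = 0.785 with an estimated correlation. Of 20 interferon response genes, Oasl2 rose 2.41-fold (3 rose adjusted over the list alone; adjusted p = 0.264 and 0.0926 without control replicate 1 or 2, and 0.0508 without Cre-positive replicate 4). Of 14 MHC class II genes, H2-Ob rose 1.37-fold (2 adjusted over the list alone; adjusted p = 0.144 without control replicate 1). Of 11 epithelial genes known to be repressed by ZEB factors, Epcam rose and 10 did not pass, the same adjusted over the list alone. Of 6 E protein and Id genes, Id2 rose and Tcf3 fell 1.35-fold (adjusted p = 0.5 without control replicate 1, and 0.0724 and 0.0793 without Cre-positive replicate 1 or 2), the same adjusted over the list alone; the median log2 fold change was -0.18, the mean 0.20 and the test up. Id2 was the single change among 20 lineage transcription factors, also adjusted over the list alone. No TGF-beta or early response and heat shock gene passed, nor adjusted over the list alone. In cDC2 with the deletion, 71 genes were higher and 71 lower without control replicate 1, and without control replicate 2, 145 and 204. DESeq2 called 469 higher and 471 lower, and with pooled controls 461 were higher.

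Few genes changed in cDC1 with the deletion, where Zeb2 was low to begin with. Itgad, which encodes an integrin alpha chain, rose 4.86-fold (9.68 ± 1.43 against 2.00 ± 0.971 CPM, SD, n = 4 and 2), and Plcb4, a phospholipase C, 1.84-fold (23.7 ± 1.09 against 12.8 ± 2.18 CPM). Both also rose in Cre-positive cDC1 of the transgene line (log2 fold change 1.04 and 0.50) and in Cre-positive cDC2 of both lines. Their rise here can therefore not be put down to the loss of Zeb2. Zfp831 had 89 counts with the deletion and 2 in the controls, a ratio of 23.3 (95% counting interval 6.27 to 196). These 3 genes were higher and 0 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 5.74e-05, 0.0163 and 0.0211), 633 genes had an unadjusted p under 0.05, and DESeq2 called 6 higher and 2 lower. Without control replicate 2, Itgad alone was called, with an adjusted p of 0.371 for Plcb4 and 0.356 for Zfp831. Zfp831 had no count in control replicate 2, and its adjusted p was 0.131 without control replicate 1 and 0.0618 without Cre-positive replicate 4. Leaving out control replicate 1 gave 2 lower genes, and Cre-positive replicate 3, 1. A fit of those 6 libraries alone called 0 higher and 1 lower, and pooled controls gave 6 and 1. No list member passed over all genes, and adjusted over the list alone 2 pDC genes rose. Set tests passed for pDC (adjusted p = 0.00234, and adjusted p = 0.495 with an estimated correlation), maturation (0.00188) and lineage factor genes (0.0442), all higher, and for cell cycle genes, lower (median log2 fold change -0.20, adjusted p = 3.85e-05). The last 3 had an adjusted p = 0.785 with an estimated correlation. No other list passed there. The median and the test differed in sign for cDC2 identity (-0.01, test up), T cell (-0.21, test up), red pulp macrophage (0.05, test down), NK cell (0.05, test down) and E protein genes (-0.01, test up).

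Gain of Zeb2 in cDC2, where the gene was already high, changed fewer genes than in cDC1. The chemokines Ccl3 and Ccl4 rose 4.75-fold (205 ± 69.7 against 43.2 ± 16.1 CPM, SD, n = 4 and 2) and 4.35-fold, and Plk2 3.02-fold, while Cdh17, a cadherin, fell 26.4-fold (0.968 ± 0.435 against 26 ± 3.46 CPM), Serpinb2 13.1-fold and Hdc, the enzyme of histamine synthesis, 4.64-fold. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 15 genes were higher and 28 lower. Snx22 fell 3.92-fold, Ifitm1 4.19-fold, Pglyrp2 3.87-fold and Prss57 3.27-fold, and Gp2 (4.77-fold) and Palld (2.78-fold) rose. Plce1 had no count with the transgene and 51 in the controls, at least 7.83-fold lower against the floor of 3 counts per library. Genes of the early response and heat shock list were higher in the same libraries (median log2 fold change 0.71, adjusted p = 1.74e-09, and adjusted p = 0.109 with an estimated correlation), with 0 of 20 members past the threshold over all genes and 5 adjusted over the list alone. The mean log2 CPM of that list was 8.956 and 8.957 in the controls and 9.438, 9.478, 9.853 and 9.714 with the transgene. Cre-positive replicates 1 and 2 differed less from each other (chi-square per gene 10.11), as did 3 and 4 (16.67), than pairs across them (32.32 to 40.72). Ccl3 moved with that split (141, 149, 268 and 263 CPM in replicates 1 to 4), and so did Ccl4 (369, 441, 714 and 823 CPM). The maturation list was also higher (median 0.37, adjusted p = 0.00526, and adjusted p = 0.785 with an estimated correlation), with no member passing. Of 19 cDC1 identity genes, Snx22 alone passed, and adjusted over the list alone 7 rose and 2 fell. Of 14 MHC class II genes, H2-Ob fell 1.42-fold (2 fell adjusted over the list alone), and of 19 pDC genes Cox6a2 rose (1 rose and 1 fell adjusted over the list alone). No gene of the other 14 lists passed, and adjusted over the list alone 4 of them had 1 member higher, 2 had 1 lower and the B cell list 2 lower. The B cell list differed in sign between its median (0.02) and its mean (-0.20, test down).

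Calls in cDC2 with the transgene were sensitive to the 2 controls. There were 4 genes higher and 17 lower without control replicate 1, and without control replicate 2, 7 and 11. Without control replicate 1 the adjusted p was 0.0618 for Ccl3, 0.345 for Ccl4, 0.252 for Plk2, 0.223 for Gp2, 0.413 for Palld, 0.0956 for Pglyrp2 and 0.0693 for Hdc. Without control replicate 2 it was 0.104 for Ccl4, 0.344 for Plk2, 0.257 for Palld, 0.319 for Prss57, 0.15 for Pglyrp2, 0.0684 for Hdc, 0.184 for H2-Ob and 0.553 for Plce1. Leaving out Cre-positive replicate 1, 2, 3 or 4 gave 0.0555 to 0.0624 for Plce1, replicate 3 or 4 gave 0.0597 and 0.0593 for Plk2, and replicate 2, 3 or 4 gave 0.0555 to 0.0746 for Palld. DESeq2 called 67 higher and 63 lower, no filter on low counts gave 36 higher, a fit of those 6 libraries alone 26 higher and pooled controls 29 higher. Ccl4 stood at 135 ± 43 CPM in these controls and 587 ± 216 CPM with the transgene, and Plk2 at 51 ± 4.8 and 154 ± 44.2 CPM. Control cDC2 of the deletion line, without added Zeb2, held 492 ± 211 CPM of Ccl4 and 162 ± 1.21 CPM of Plk2. The Cre-positive means were thus near those of the other line's controls, although neither gene was called between the controls. Ccl3 also differed between the controls of the lines, at 171 ± 37.5 CPM in the deletion line against 43.2 ± 16.1 CPM here (adjusted p = 0.0117, and 0.36 without control replicate 1 of this line and 0.111 without control replicate 2 of the other).

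**Figure D2:**
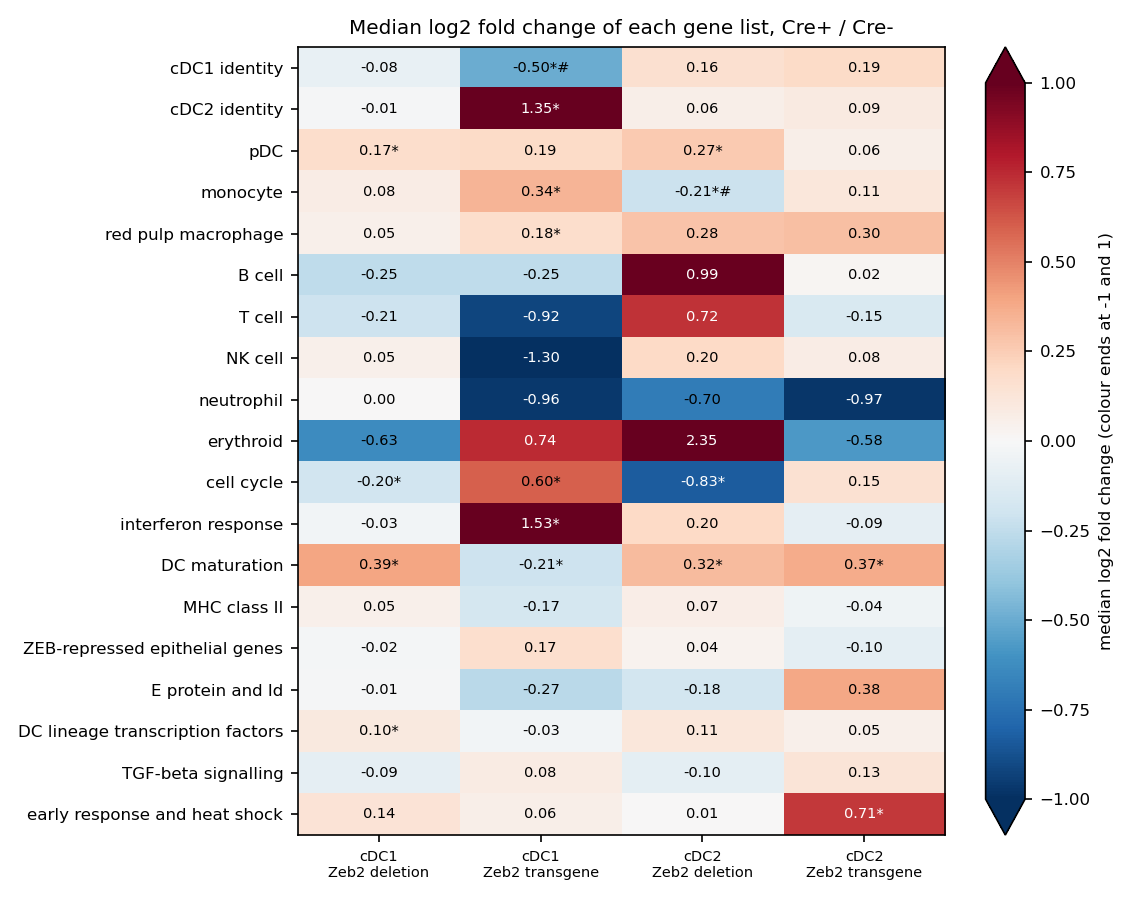
Median log2 fold change of each of the 19 gene lists (lines) in the 4 comparisons of Cre-positive with Cre-negative libraries (columns); a star marks an adjusted p under 0.05 by camera with a preset correlation and # with an estimated one. The cell cycle list stands at -0.83 in cDC2 with the deletion and 0.60 in cDC1 with the transgene.

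Subset signatures gave a wider view than the lists. For each line they were taken from the controls of the other line, as genes at least 4-fold apart between cDC1 and cDC2, so that no library served in both steps. In cDC1 with the transgene the 481 genes of the cDC1 signature had a median log2 fold change of -0.56 (4 rose and 104 fell; camera adjusted p = 1.75e-27, and adjusted p = 7.36e-05 with an estimated correlation). The 912 genes of the cDC2 signature had a median of 0.61 (178 rose and 14 fell; adjusted p = 2.35e-14, and adjusted p = 0.0196 with an estimated correlation; median 0.97 without control replicate 1). In cDC2 with the deletion the cDC1 signature of 487 genes had a median of 0.19 (50 rose and 24 fell; adjusted p = 0.014, adjusted p = 0.483 with an estimated correlation, adjusted p = 0.0544 with no filter on low counts and 0.112 without control replicate 2; median 0.08 without Cre-positive replicate 2). The cDC2 signature of 930 genes, with 24 higher and 33 lower, did not pass there (median 0.05, test down, adjusted p = 0.942). In cDC1 with the deletion the medians were -0.04 for the cDC1 signature (adjusted p = 0.0594) and 0.09 for the cDC2 signature (adjusted p = 0.0869). The first passed without control replicate 1 (adjusted p = 0.0277) or Cre-positive replicate 2 (0.0114) or 3 (0.0417), and the second without control replicate 2 (0.0315) or Cre-positive replicate 1 (0.00703). In cDC2 with the transgene the medians were 0.09 (adjusted p = 0.471) and 0.02 (adjusted p = 0.786, test down; median -0.01 without control replicate 1 or Cre-positive replicate 4).

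**Figure D3:**
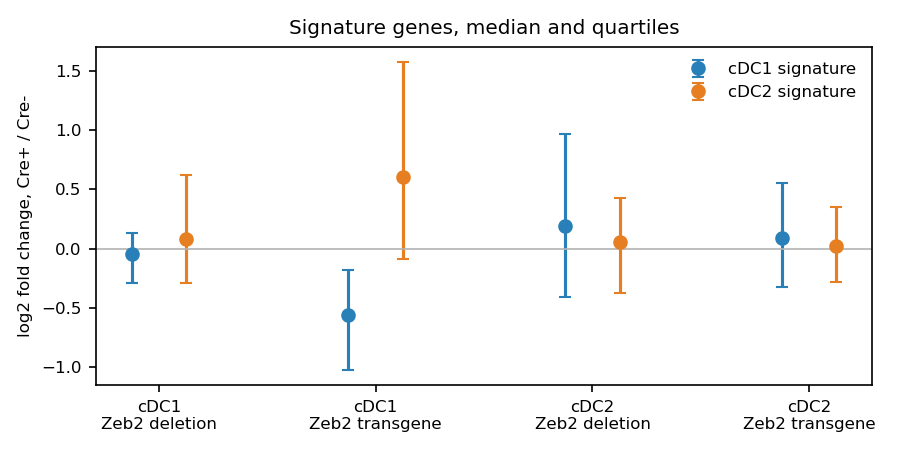
Median (point) and quartiles (bars) of the log2 fold change of the cDC1 and cDC2 signature genes in each comparison of Cre-positive with Cre-negative libraries. In cDC1 with the transgene the cDC1 signature lies at -0.56 and the cDC2 signature at 0.61, and the other medians lie between -0.04 and 0.19.

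Loss and gain of Zeb2 moved a set of cDC2 genes in opposite directions. Cdh17 rose 7.35-fold with the deletion (128 ± 33.4 against 17.4 ± 5.56 CPM) and fell 26.4-fold with the transgene, and Lsr, a lipoprotein receptor of tight junctions, rose 4.03-fold and fell 2.79-fold. Snx22, Hdc, Lurap1 and Plce1 also rose with the deletion and fell with the transgene. Gp2, a surface glycoprotein, fell with the deletion and rose with the transgene. In all, 20 genes passed in both comparisons with opposite signs, 19 of them higher with the deletion, against 0.653 and 0.432 expected for the directions from the products of the counts, and 4 passed with the same sign. The comparisons share no library. The count of 20 was 10 without control replicate 1 of the transgene line, 7 without its control replicate 2, 10 without control replicate 1 of the deletion line, 50 by DESeq2 and 9 among genes changed at least 2-fold in both. With the deletion, the adjusted p without control replicate 1 was 0.0521 for Cdh17 and 0.197 for Hdc, and without control replicate 2 it was 0.0544 for Lurap1. With the transgene, that of Lurap1 was 0.319 without control replicate 2 and 0.0588 without Cre-positive replicate 4. That of Gp2 was 0.223 without control replicate 1, that of Hdc 0.0693 and 0.0684 without control replicate 1 or 2, and that of Plce1 0.553 without control replicate 2. In cDC1, 0 genes passed with opposite signs and 2 with the same sign by edgeR, with 633 and 2599 genes at an unadjusted p under 0.05 in its comparisons, and DESeq2 and the fit without Cre-positive replicate 3 of the deletion line each gave 1 with opposite signs.

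The 4 cDC2 genes that rose in both lines were Itgad, Cox6a2, Plcb1 and Plcb4, picked out after their values were seen. Itgad rose 10.4-fold with the deletion (66.6 ± 8.89 against 6.42 ± 0.321 CPM) and 6.96-fold with the transgene, and Plcb4 11.6-fold (34.6 ± 2.78 against 2.98 ± 0.303 CPM) and 14.6-fold (31.8 ± 3.91 against 2.18 ± 0.193 CPM). Cox6a2, a subunit of cytochrome c oxidase and also on the pDC list, rose 36.6-fold and 18-fold. Plcb1 had 1759 counts against 1 with the deletion (ratio 904, 95% counting interval 162 to 35700) and 451 against 2 with the transgene (ratio 120, 33.0 to 993). The adjusted p of these genes was between 1.33e-12 and 1.04e-05 in cDC2. In cDC1 all had log2 fold changes above 0, and those past the threshold were Itgad and Plcb4 in both lines and Plcb1 with the transgene. Of these, Plcb4 with the transgene (adjusted p = 0.165 and 0.122) lost its call without control replicate 1 or 2, Plcb4 with the deletion without control replicate 2 (0.371) and Itgad with the transgene without control replicate 1 (0.108). Plcb4 with the transgene also had an adjusted p of 0.0636 and 0.0588 without Cre-positive replicate 3 or 4. Itgad lies on chromosome 7 from 128173933 to 128205504, and Cox6a2, which overlaps its end, from 128205435 to 128206366, so the split of reads between these neighbours is uncertain because the strand of counting is not stated. Itgax, the gene of CD11c, whose sequences drive Cre, lies beside them from 128129526 to 128150657 and had log2 fold changes of 0.20 to 0.34 that did not pass. Plcb1 (134786164 to 135475258) and Plcb4 (135658603 to 136014602) are neighbours on chromosome 2.

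**Figure D4:**
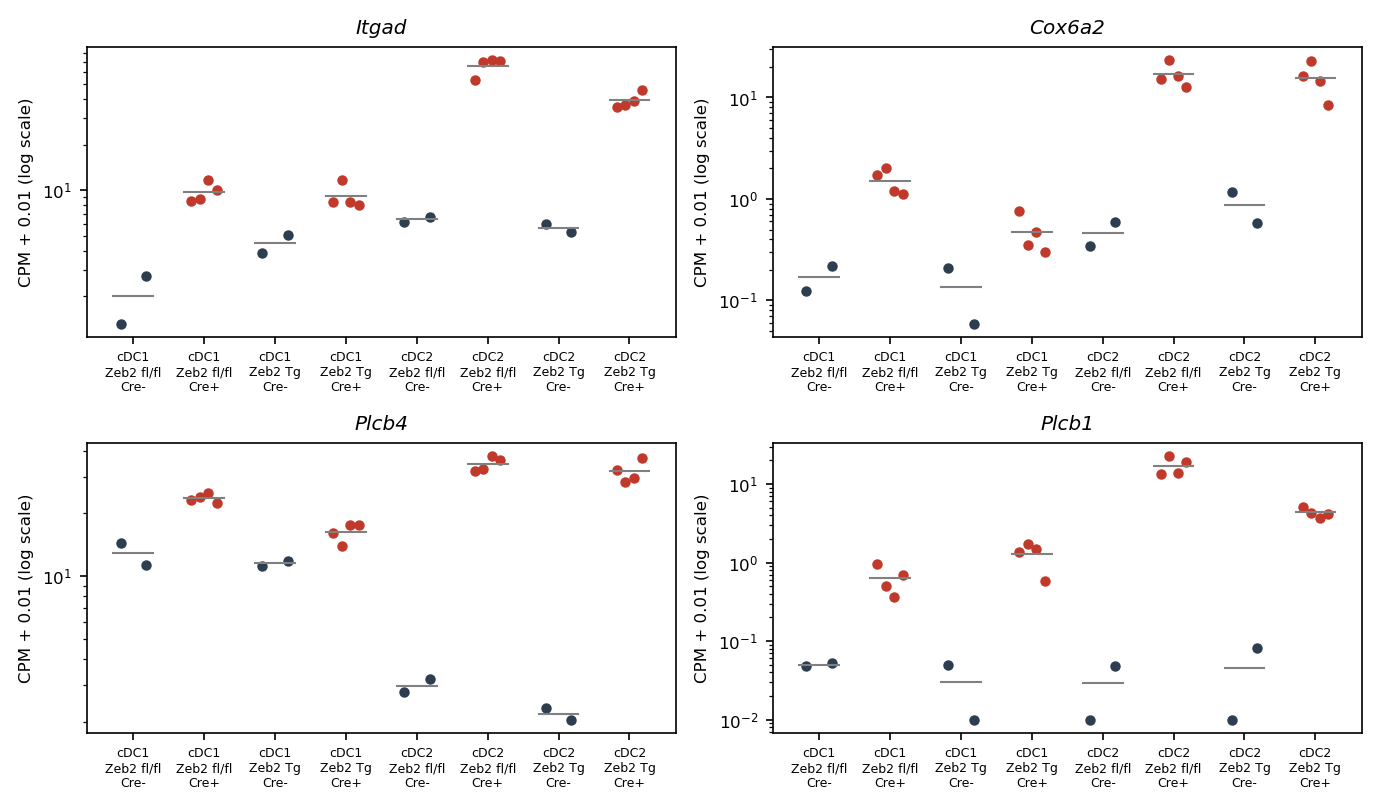
CPM of Itgad, Cox6a2, Plcb4 and Plcb1 in each of the 24 libraries (log axis after adding 0.01 CPM; points are libraries, grey bars group means, red Cre-positive). In cDC2, Plcb4 rises from 2.98 to 34.6 CPM in the deletion line and from 2.18 to 31.8 CPM in the transgene line.

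Whether the response differed between subsets was tested as an interaction within each line. With the deletion, Ttc39a rose more in cDC2 than in cDC1 (difference of log2 fold changes 4.39, SE 0.48, adjusted p = 1.37e-05), and so did Id2 (1.21, adjusted p = 0.00617; 0.0549 without control replicate 1 of cDC1 and 0.0977 without control replicate 1 of cDC2). Gp2 fell more in cDC2 (-3.34; adjusted p = 0.0535 without control replicate 1 of cDC2). The effect of the transgene on Zeb2 itself was smaller in cDC2 than in cDC1 on the log2 scale (-3.41, SE 0.46, adjusted p = 0.000126), while the mean rose from 104 to 153 CPM in cDC2 and from 2.81 to 44.2 CPM in cDC1. The effect on Ltbp2 (3.79) and Dnajc22 (4.53) lay above that in cDC1, where both fell. By edgeR's quasi-likelihood test, the effect of the deletion differed between subsets for 142 genes (77 with a higher fold change in cDC2 and 65 with a lower) and that of the transgene for 264 (108 and 156). Of 17 monocyte genes, 4 had a lower fold change in cDC2 than in cDC1 with the deletion (7 adjusted over the list alone; adjusted p = 3.8e-09, and 0.00293 with an estimated correlation). With the transgene, of 20 interferon response genes, 8 had a lower fold change in cDC2 (adjusted p = 1.65e-20, and adjusted p = 0.0128 with an estimated correlation, 0.0955 when blocked by replicate number), as had 7 of 20 cDC2 identity genes (adjusted p = 1.79e-12, and 0.0417 with an estimated correlation, 0.259 when blocked), while 5 of 19 cDC1 identity genes had a higher and 1 a lower one (5.49e-12, and 0.00914 with an estimated correlation, 0.0955 when blocked). Adjusted over the list alone these counts were 1 higher and 13 lower, 1 and 9, and 12 and 1. For the deletion the count of 142 was 51 and 61 without control replicate 1 or 2 of cDC1, 90 without Cre-positive replicate 1 of cDC1, 21 without control replicate 1 of cDC2 and 351 by DESeq2. For the transgene the count of 264 was 140 without control replicate 2 of cDC1, 138 and 173 without control replicate 1 or 2 of cDC2, 471 by DESeq2 and 400 with the replicate number as a block, where the erythroid list passed too (adjusted p = 0.035, against 0.161 without the block; 0.259 with an estimated correlation, and no member called).

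Controls of the 2 lines were also compared, as the size of differences that do not involve Cre. The Rosa26 transcript Gt(ROSA)26Sor was lower in the transgene line, at 0.217 ± 0.25 against 17.3 ± 2.76 CPM in cDC1 (SD, n = 2 each), 83.4-fold, and in cDC2 at 3 counts against 372 (ratio 130, 95% counting interval 44.0 to 631; no count in control replicate 2 of the transgene line). Nnt, a mitochondrial transhydrogenase that is partly deleted in the C57BL/6J substrain, was 3.05-fold lower in cDC1 and 3.66-fold lower in cDC2 of the transgene line, and Wdfy1 7.72-fold and 3.51-fold lower. Hebp1, a heme-binding protein, was 52.0-fold and 40.2-fold higher, Ifih1, a sensor of viral RNA, 3.25-fold and 3.28-fold, and Scn3a 125-fold higher in cDC2. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 17 genes differed in cDC1 (6 higher and 11 lower in the transgene line) and 18 in cDC2 (11 and 7). In cDC1 the count was 8 and 9 without control replicate 1 or 2 of the deletion line, 51 by DESeq2 and 6 in a fit of those libraries alone. In cDC2 it was 9 and 11 without control replicate 1 or 2 of the deletion line, 70 by DESeq2, 85 in a fit of those libraries alone and 30 with no filter on low counts.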

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

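The tests of explanations in this part, the splits of the controls among them, were chosen after the results they address had been seen, whereas the interaction tests and the search for libraries far from their group were planned.

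The effect of Cre differed between the subsets by an interaction test for 142 genes in the deletion line and 264 in the transgene line. In the deletion line the differences of log2 fold changes (cDC2 minus cDC1) were 4.793 for Clec4b2, 4.51 for Igf2r, 4.456 for Plce1, 4.394 for Ttc39a, 1.205 for Id2, -2.558 for Il27ra, -2.82 for Itga8, -3.338 for Gp2 and -4.033 for Zfp831. In the transgene line they were 4.525 for Dnajc22, 3.825 for Mab21l3, 3.791 for Ltbp2, 3.47 for Ttc39a, -3.405 for Zeb2, -5.899 for Ifit3b, -6.628 for Ptger3, -6.718 for Clec4a4 and -7.048 for Plce1. Leaving out single libraries removed the calls of all of these but Ttc39a in both lines and Dnajc22, Ltbp2, Zeb2, Ifit3b and Clec4a4 in the transgene line. The lost calls had adjusted p-values by edgeR of up to 0.147 for Clec4b2, 0.358 for Igf2r, 0.163 for Plce1, 0.0977 for Id2, 0.329 for Il27ra, 0.241 for Itga8, 0.0535 for Gp2 and 0.116 for Zfp831 with the deletion, and 0.31 for Mab21l3, 0.0605 for Ptger3 and 0.294 for Plce1 with the transgene. The libraries behind these values are control replicate 1 of cDC2 for Clec4b2, Igf2r, Plce1, Id2, Itga8, Gp2 and Mab21l3, control replicate 1 of cDC1 for Il27ra, control replicate 2 of cDC1 for Zfp831 and Ptger3, and control replicate 2 of cDC2 for Plce1 with the transgene. In the transgene line Plce1 had no count in Cre-positive cDC2, so its difference there is a fitted value and no bound. With the replicate number as a block, 400 genes were called in the transgene line, and Plce1 was not (adjusted p = 0.0538).

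A single library stood far from the other 3 of its group for 3 of 141 pairs of a named gene and a Cre-positive group, where chance gives about 1 in 20, or 7.05. Itgad was at 11.7 CPM in replicate 2 of cDC1 with the transgene (others 8.03 to 8.41) and at 53.3 CPM in replicate 1 of cDC2 with the deletion (others 70.0 to 72.2). Cd200 was at 9.97 CPM in replicate 4 of cDC1 with the transgene (others 13.5 to 13.6).

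Itgad, Cox6a2, Plcb1 and Plcb4 were picked for rising in Cre-positive cDC2 of both lines, so their signs there are no test. A response to the level of Zeb2 would leave them as they were in cDC1 with the deletion, if Zeb2 did not change there. Yet 4 of the 4 genes were higher in those cDC1 with adjustment over these genes. Itgad and Plcb4 were already known to be called in that comparison. Zeb2 did not pass there, but at 1.22 against 1.53 CPM for the whole gene the count cannot show whether intact Zeb2 was lost. This test therefore cannot exclude such a response. DNA carried in with the Cre driver, as its integrated construct or the genes linked to it, would place them close together: 2 pairs lay within 1 Mb of each other, and of 10000 random sets of 4 tested genes a share of 2e-04 had as many. Itgad and Cox6a2 lie 23.3 and 54.8 kb from Itgax, the source of the driver, so copies of these genes in the construct could add their transcripts, and the neighbours Plcb1 and Plcb4 could lie near its place of insertion. The DNA of the driver was not examined, and an effect of Cre itself stays open and untested.

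In cDC1 with the transgene, cDC2 genes rose and cDC1 genes fell. Carried-over cDC2 cells would bring all their abundant transcripts in 1 proportion. The share of cDC2 RNA needed was taken over 34 genes abundant in transgenic cDC2 and scarce in control cDC1. Its upper quartile was 5.62 times the lower or more in each of the 4 libraries (0.894 to 6.11%, 0.633 to 6.33%, 0.0214 to 3.1% and 0.247 to 1.39% in replicates 1 to 4). For some genes the share fell below 0 (to -0.966% for Bmp2). The lower quartiles are thus of the size of noise, and their ratio alone cannot exclude an even share. Single abundant genes differed beyond that noise, with 1.37 to 2.19% for Ptgs2, 11.1 to 18.4% for Tgm2 and 20.6 to 73.2% for Clec7a. Dilution by carried-over cDC2 cells would lower cDC1 genes by a few percent. The median fall of 481 cDC1 signature genes was 24.8% or more in each library. A response to the level of Zeb2 predicts opposite changes where Zeb2 is lost. Of 106 cDC1 signature genes from this line's controls that fell here, 29 rose and 2 fell in cDC2 with the deletion (exact sign test over genes, p = 4.63e-07). That test assumes an even split and independent genes, whereas of all 487 genes of the signature 50 rose there and 24 fell. Its p therefore overstates the evidence, although 29 to 2 is more one-sided than 50 to 24. Of 190 cDC2 signature genes that rose here, 5 fell and 3 rose (same exact test, p = 0.727), with a median log2 fold change of -0.05, which decides nothing for the cDC2 genes. Zeb2 was even over these libraries (44.3, 45, 46.2 and 41.3 CPM) while Sirpa (115, 117, 53.1 and 36.2 CPM) and the median share needed (3.06, 2.81, 1.49 and 0.548%) were not. Carry-over in 1 proportion is thus excluded only as the cause of all these changes together, since it cannot give both the Ptgs2 and the Tgm2 values. A varying part from cDC2 cells, cells with another profile, or a change in which cells fall in the sort gate stay open.

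The controls of the lines differed although neither carries Cre. Beside the Rosa26 transcript, 28 genes passed in cDC1 or cDC2, and 15 of them lie on the chromosomes of Zeb2 and Rosa26, against 3.64 expected from the 13% of 13133 tested genes with a position there (one-sided Fisher's exact test, p = 3.44e-07). DNA flanking the engineered loci, kept from another strain, could carry such differences. Each line's own littermates share part of that DNA, and a biological difference between the lines was not tested and stays open.

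For the control subsets, the real grouping into cDC2 and cDC1 gave 6212 genes in the fit used for splits. Of the 35 splits of the 8 libraries, 1 gave as many (the real one), and the highest of the others gave 0. Each of the others mixes the subsets and so widens the spread within groups, which makes a low count likely whatever the cause. A share of 1 in 35 is under 0.05 but is the smallest this test can give, so it cannot say more about chance.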

How the results depend on the processing

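The fit of replicates 3 and 4 alone for Cre-positive cDC1 of the transgene line was chosen after seeing the data, and the other alternatives were planned. With it, all 7 results recomputed kept their direction and stayed within 1.5 times or on their side of the threshold (328 genes higher, 320 lower), and 9 of 72 named genes lost their calls. DESeq2's size factors in edgeR changed none of 28 results and none of 270 named genes. With no low-count filter, 36 genes were higher in cDC2 with the transgene, 30 differed between the control cDC2 of the lines, and the cDC1 signature in cDC2 with the deletion had a median of 0.186 and no longer passed; with the stricter filter the cDC2 signature in cDC1 with the deletion passed at 0.132. A 2-fold minimum left 228 higher and 179 lower genes in cDC1 with the transgene, 125 and 119 in cDC2 with the deletion, 17 lower in cDC2 with the transgene, 1828 and 1193 higher in control cDC2 and cDC1, 88 in the interaction of the deletion line and 9 opposite in cDC2, because fewer genes meet both limits. DESeq2 called 6 higher and 2 lower in cDC1 with the deletion, 469 higher in cDC2 with the deletion, 67 higher and 63 lower in cDC2 with the transgene, 351 and 471 in the interactions, 1 opposite in cDC1 and 50 in cDC2, and 51 and 70 between the line controls of cDC1 and cDC2. Fits of the compared libraries alone gave 0 higher and 1 lower in cDC1 with the deletion, 251 and 299 in cDC1 with the transgene, 26 higher in cDC2 with the transgene, 6 and 85 for the line controls of cDC1 and cDC2, and a log2 fold change of Zeb2 in cDC2 with the transgene of 0.55, which passed. Pooled controls gave 6 higher and 1 lower in cDC1 with the deletion, 1059 and 856 in cDC1 with the transgene, 461 higher in cDC2 with the deletion and 29 in cDC2 with the transgene, and turned the sign of Id2 in cDC1 with the deletion (0.0207) and in cDC2 with the transgene (0.0289), and of Slc4a1 (-0.0759) and Cd8b1 (-0.0272) in cDC2 with the deletion. Camera with an estimated correlation passed 2 list tests and fry 8, against 17 with the preset, and with an estimated correlation the cDC1 signature in cDC2 with the deletion (0.192) no longer passed. Signatures from both lines, which share controls with the comparison, gave -0.0572 and 0.162 for the cDC1 and cDC2 signature in cDC1 with the deletion and 0.199 for the cDC1 signature in cDC2 with the transgene, all past the threshold, and -0.0387 for the cDC2 signature there, of opposite sign. Of the named genes, DESeq2 lost the calls of 3 and gained 1 of 270, no filter gained 1 of 270, the stricter filter changed none of 261, fits of the compared libraries alone lost 30 of 268, and pooled controls lost 8, gained 5 and turned the sign of 4 of 138. Except where stated, the cause was not tested.

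The labels do not say what the replicate numbers mark, and outside the pairs across subsets of the transgene line, libraries with the same number did not all deviate together (r of -0.0406 to 0.301 for the pairs across subsets of the deletion line, -0.201 to 0.158 for 8 pairs within a subset and line, and -0.168 to -0.06 for 4 pairs of line controls), although 10 of the 12 pairs across subsets had r above 0.1, the other 2 being the deletion line's controls, and 19 of 24 libraries correlated best with their own number. With the replicate number as a replicate block, 7 genes were higher and 1 lower in cDC1 with the deletion, 226 lower in cDC2 with the deletion, 18 lower in cDC2 with the transgene, 400 in the interaction of the transgene line, 1 opposite in cDC1 and 13 in cDC2, and 30 between the cDC2 line controls. In the interaction of the deletion line, 82 genes had a higher and 58 a lower fold change in cDC2 with that block. Id2 in cDC1 with the deletion turned to 0.021, the cDC1 signature in cDC2 with the transgene passed at 0.0593, and the cDC2 signature there turned to -0.0231. The block changed 7 calls of lists: in cDC1 with the deletion the macrophage, B cell and MHC class II lists passed, in cDC1 with the transgene the maturation list did not (adjusted p = 0.0817), and in cDC2 with the transgene the cDC1 identity, pDC and B cell lists passed. Of 270 named genes, 29 lost their calls, 1 gained one and 1 changed sign. In the interaction of the transgene line it ended the call of Plce1 (adjusted p = 0.0538), added that of the erythroid list (0.035; 0.259 with an estimated correlation, and no member called) and changed no other call of a named gene or, at the preset correlation, of a list. With an estimated correlation it ended the calls of the interferon response (0.0955), cDC1 identity (0.0955) and cDC2 identity lists (0.259) there. The cause was not tested.

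Leaving out each library in turn, a lone control being assumed to vary like the other groups, gave 1 to 3 higher and 0 to 2 lower genes in cDC1 with the deletion, 264 to 516 and 212 to 466 in cDC1 with the transgene, 71 to 291 and 71 to 382 in cDC2 with the deletion, 4 to 17 and 11 to 28 in cDC2 with the transgene, and 3229 to 3327 and 3098 to 3230 higher in control cDC2 and cDC1. The interactions ran from 21 to 161 in the deletion line and 138 to 335 in the transgene line, opposite genes from 0 to 1 in cDC1 and 7 to 20 in cDC2, and line controls from 8 to 12 in cDC1 and 9 to 12 in cDC2. The medians of the cDC1 and cDC2 signature ran from -0.0763 to -0.0109 and 0.0384 to 0.226 in cDC1 with the deletion, -0.598 to -0.447 and 0.494 to 0.97 in cDC1 with the transgene, 0.0829 to 0.228 and 0.00346 to 0.0763 in cDC2 with the deletion, and 0.0374 to 0.12 and -0.0115 to 0.0589 in cDC2 with the transgene. The log2 fold change of Zeb2 ran from -1.10 to 1.31 in cDC1 with the deletion, 3.77 to 4.23 in cDC1 with the transgene, -2.30 to -1.89 in cDC2 with the deletion and 0.54 to 0.57 in cDC2 with the transgene, and that of Id2 in cDC1 with the deletion from -0.185 to 0.0596, the latter without control replicate 1. Of 255 called named genes, 88 lost their call in at least 1 of these fits and 167 did not. Fewer libraries remain in such fits, and the cause was otherwise not tested.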

Other observations

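The overlap test in this part was chosen after the results it measures had been seen, and so were the genes named here.

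Loss of Zeb2 in cDC2 and gain of Zeb2 in cDC1 moved many of the same genes in opposite directions, in comparisons that share no library. Of the genes past the threshold in both by edgeR, 110 were higher with the deletion in cDC2 and lower with the transgene in cDC1, against 10.5 expected from the counts (Fisher's exact test, p = 1e-84). Another 61 went the other way, against 13.6 (same exact test, p = 1.32e-23). This test treats genes as independent, but many, such as the cell cycle genes, change together. Its p-values therefore overstate the evidence and do not measure the spread between libraries. Together these 171 opposite genes stand against 24.1 expected, and the 16 genes that moved the same way against 24 expected. Among the first were Ttc39a (log2 fold change 4.43 in cDC2 and -4.05 in cDC1), Fcrla (3.70 and -3.57), Lsr (2.01 and -2.01) and the chemokine receptor Cxcr3 (2.52 and -1.82). Among the second were Clec1b (-1.90 and 4.10), Wfdc17 (-1.50 and 3.79) and the cell cycle genes Top2a (-1.05 and 0.99), Ccnb1 (-0.995 and 0.92) and Aurkb (-0.93 and 0.90). The transgene calls of Top2a and Ccnb1 were lost without control replicate 1 (adjusted p = 0.0933 and 0.0943) or 2 (0.115 and 0.124) of that group, and that of Aurkb without control replicate 1 (0.0666).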
